A study of Homo sapiens with 6 samples.

How the data were processed

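RNA was sequenced from 6 libraries of HMCB, a human melanoma cell line that the labels give as carrying an NRAS Q61K mutation. Cells had been transfected with a control siRNA (siNC, 3 libraries) or with an siRNA against AHCYL1 (siAHCYL1, 3 libraries), and RNA was taken 3 days later, per the series design. Per the labels' protocols, total RNA was extracted with a column kit and made into non-directional libraries for Illumina sequencing. Reads from a gene and from an overlapping or antisense gene on the other strand can therefore not be told apart. The labels call the replicates biological without naming separate cultures, so the p-values measure the spread between these samples, which may be partly technical.

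The authors deposited 1 table of TPM, a transcript abundance unit that divides by transcript length and scales each library to a fixed total. Per the submitters' processing notes, STAR, RSEM and the GRCh38 build were used, and their versions and the gene annotation are not given in the sources used here. The table holds 26902 gene symbols, of which 25370 matched a current symbol or a synonym. Each library's TPM summed to the same total within rounding, so the table keeps no sequencing depth, the depth is unknown, and no counting interval or detection limit was computed. The table's 92 spike-in rows were at 0 in every library, and 8773 genes were at 0 in all 6. No row was named as a mitochondrially encoded gene, and that list was not analysed here. The columns of the control libraries carry the prefix nc and those of the AHCYL1 libraries the prefix si, and the second was assigned because only 1 other group exists.

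From these values, log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3, using a moderated test with an intensity trend, two-sided, with Benjamini-Hochberg adjustment. Genes with at least 1 TPM in at least 3 of the 6 libraries were kept, which left 13266. A gene was counted as changed at an adjusted p under 0.05, and fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. The model held the group and no other term. Means are given with the SD over 3 libraries, and log2 fold changes with their standard error (SE). AHCYL1 was also tested with an exact permutation test, whose smallest possible two-sided p with 3 libraries against 3 is 0.1.

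Before the data were examined, 30 gene lists were fixed from textbook knowledge, of which 29 had members to test. They covered ER chaperones and ER-associated degradation, the integrated stress response, ER and store-operated calcium handling, calcium-responsive NFAT and CREB targets, AHCYL1 paralogs and binding partners, the methionine cycle, G1/S and DNA replication, G2/M and mitosis, p53 targets, apoptosis regulators, MAPK pathway output, the melanocytic lineage, the dedifferentiated invasive melanoma state, interferon-stimulated genes, NF-kB targets, cholesterol biosynthesis and SREBP targets, glycolysis and hypoxia, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, lysosome and autophagy, ER to Golgi trafficking, NRF2 targets, HSF1 targets, extracellular matrix and TGF-beta targets, replication-dependent histones, and markers of keratinocytes and epithelia, fibroblasts, immune and blood cells, and endothelium. Of 833 list entries, 811 were found in the table. Each list was tested against all other genes with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the 29 lists, and again with the correlation estimated from the data. The directional test of fry, which asks only whether the members of a list move one way on balance, was an alternative.

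The genes named were set by a rule fixed at the same time, except for 3 collagen genes in the closing section. It took AHCYL1, AHCY, AHCYL2 and the 3 IP3 receptor genes with any result. It took the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap and whose higher mean was at least 5 TPM. From each list it took up to 4 changed members, smallest adjusted p first, and the member that went most against its list. Some genes that the rule takes are not reported here. The alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, the replicate number as a block, no intensity trend with robust moderation, and each library left out in turn. Chosen after seeing the data were a fit without replicate 1 of both groups, a fit with the trend over transcript length and GC content removed, and a fit without genes carrying 7-mers described in the closing section.

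In simulated libraries with 200 of 13266 genes changed, the comparison of siAHCYL1 with siNC recovered 67% of them at a log2 fold change of 0.5, 99% at 1 and 100% at 2, with 5, 16 and 17 false calls. The data had many more changed genes (6844), and the Benjamini-Hochberg cutoff depends on their share. These recovery rates and false calls therefore do not carry over to the real comparison. For the 7-mer scan, 3′ UTRs and transcript lengths came from GENCODE 29 on GRCh38. UTRs of at least 30 bases and 7-mers present in at least 50 genes were used, fold changes were limited to 3 log2 units either way, AHCYL1 was left out, and UTR length and base content were in the model. The scan and the figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.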

Results

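RNA levels were compared between HMCB melanoma cells given an siRNA against AHCYL1 and cells given a control siRNA, with 3 libraries in each group. AHCYL1, also called IRBIT, is an S-adenosylhomocysteine hydrolase-like protein that binds IP3 receptors, the calcium release channels of the endoplasmic reticulum (ER). The series asks why and how AHCYL1 promotes proliferation in NRAS-mutant melanoma cells. The TPM values keep no sequencing depth, and between 13035 and 13189 genes reached 1 TPM in each library.

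The siRNA target was lower in every siAHCYL1 library. AHCYL1, at chromosome 1, positions 109984765 to 110023742 of GRCh38, had 150.02, 134.05 and 131.09 TPM in the control libraries. The libraries given the AHCYL1 siRNA had 13.45, 11.13 and 10.97 TPM. The mean went from 138.39 ± 10.2 to 11.85 ± 1.39 TPM (SD, n = 3), 8.56% of the control level or 11.7-fold lower. The log2 fold change was -3.44 (SE 0.096, limma adjusted p = 5.64e-08), and the exact permutation p was 0.1, the smallest that 3 against 3 allows. The paralogs did not pass the test, and each passed under another setting. AHCY had 274 ± 28.8 against 303 ± 9.25 TPM (log2 fold change 0.15, adjusted p = 0.127) and AHCYL2 had 15.7 ± 1.31 against 18.2 ± 1.29 TPM (0.20, adjusted p = 0.12). AHCY passed without siNC replicate 1 (0.24, adjusted p = 0.0119) and without replicate 1 of both groups (0.21, adjusted p = 0.00657), and AHCYL2 with the length and GC trend removed (0.23, adjusted p = 0.0393).

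Of the 3 IP3 receptor genes, 1 fell, 1 rose and 1 did not pass. ITPR1 fell from 8.52 ± 0.48 to 2.23 ± 0.59 TPM (log2 fold change -1.57, SE 0.15, adjusted p = 4.17e-05). ITPR3 rose from 50.8 ± 1.20 to 93.1 ± 6.37 TPM (0.86, SE 0.072, adjusted p = 1.62e-05). ITPR2 had 15.76 ± 1.02 against 16.96 ± 3.22 TPM and did not pass (0.09, adjusted p = 0.605). The 3′ UTR of ITPR2 carries GTATGCAA, and 48.3% of the 288 genes with this 8-mer fell. That of ITPR1 carries TATGCAA without GTATGCA, and of 1105 such genes 25.4% fell and 27.4% rose.

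**Figure D1:**
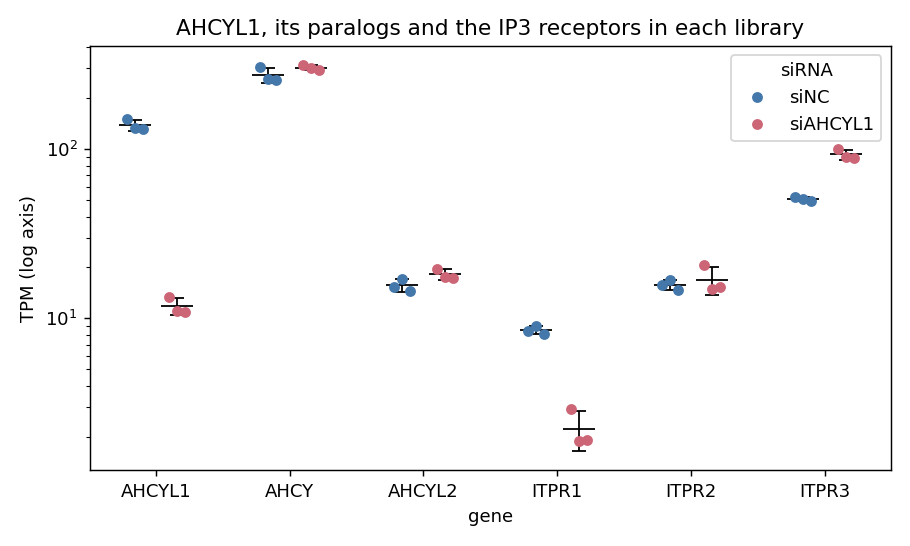
TPM on a log axis of AHCYL1, AHCY, AHCYL2, ITPR1, ITPR2 and ITPR3 in the 3 siNC (blue) and 3 siAHCYL1 (red) libraries, with black lines for the mean ± SD. AHCYL1 and ITPR1 were lower and ITPR3 and AHCYL2 higher in all 3 siAHCYL1 libraries than in any siNC library, although AHCYL2 did not pass the test (adjusted p = 0.12).

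Of 13266 genes tested, 6844 (51.6%) changed, 4030 higher and 2814 lower after the AHCYL1 siRNA. Of these, 1109 changed at least 2-fold, 640 higher and 469 lower. The higher genes made up 58.9% of calls, 50.2% under median-of-ratios scaling and 48.1% under quantile normalization. The median log2 fold change over all genes was 0.06. The groups did not overlap in 7848 genes (59.2%), where chance gives 10%. The first principal component held 75.6% of the variance and separated the groups. The second held 9.78%, with replicates 1, 2 and 3 at 15.04, -1.23 and -14.52 in siNC and at 17.57, -7.14 and -9.73 in siAHCYL1. Transcripts under 1000 bases held between 16.5% and 19.7% of TPM in siNC and between 14.7% and 18.7% in siAHCYL1, lowest in replicate 1 of each group.

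The largest rise of a gene above 0 in the controls was that of SLC6A13, a GABA and taurine transporter, from 2.66 ± 1.15 to 72.1 ± 3.59 TPM (log2 fold change 4.37). SLC15A1, the oligopeptide transporter PEPT1, rose from 5.48 ± 0.93 to 100.2 ± 3.95 TPM (3.97). SLC9A3, the sodium-proton exchanger NHE3, to which AHCYL1 is known to bind, rose from 27.3 ± 1.76 to 265 ± 13.6 TPM (3.23, SE 0.074, adjusted p = 5.64e-08). Its 3′ UTR carries TCGGAGA, the 7-mer most associated with higher fold changes, as does that of P4HB. The estimated effect over all carriers of TCGGAGA was 0.22 log2 units, far smaller than the rise of SLC9A3. Of risen genes searched 3.31% carried this 7-mer, and of fallen ones 1.62%. C15orf48 (4.02), the secreted BPIFB1 (3.84), the histone gene HIST1H2BD (3.42), the cell adhesion gene OPCML (3.39) and the neurogenic transcription factor NEUROG2 (3.29) were also among the 10 largest. SNHG9, a noncoding RNA whose gene lies beside RPS2, was listed at 0 in all 3 control libraries and at 50.98, 23.43 and 32.0 TPM after the AHCYL1 siRNA. HECTD2-AS1 (3.24) is an antisense gene, and these libraries do not tell strands apart.

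The largest falls after AHCYL1 itself included DCT, the melanin synthesis enzyme dopachrome tautomerase, from 11.4 ± 0.58 to 0.34 ± 0.25 TPM (log2 fold change -3.23). The histone gene HIST1H4C was at 7.18, 9.85 and 6.87 TPM in the controls and listed at 0 in all 3 siAHCYL1 libraries. C1QTNF4 (-3.03), the immune checkpoint receptor CTLA4 (14.5 ± 1.81 to 0.95 ± 0.38 TPM) and the lysosomal membrane gene LAPTM5 (-2.95) fell. TF, transferrin, fell from 36.4 ± 1.04 to 4.12 ± 0.25 TPM (-2.87) and SCARA5, a ferritin receptor, fell from 40.6 ± 2.54 to 5.01 ± 1.06 TPM (-2.80). ANGPT2 (-2.79) and SLC7A11, the cystine-glutamate exchanger (88.3 ± 5.14 to 12.2 ± 2.20 TPM, -2.77), completed the 10. Adjusted p was at most 8.49e-06 for each of these rises and falls. The 3′ UTRs of TF, SCARA5 and SLC7A11 carry GTATGCA, the 7-mer most associated with lower fold changes. Those of DCT, HIST1H4C, C1QTNF4, CTLA4, LAPTM5 and ANGPT2 do not. The estimated effect over all carriers of GTATGCA was -0.23 log2 units, far smaller than these falls.

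**Figure D2:**
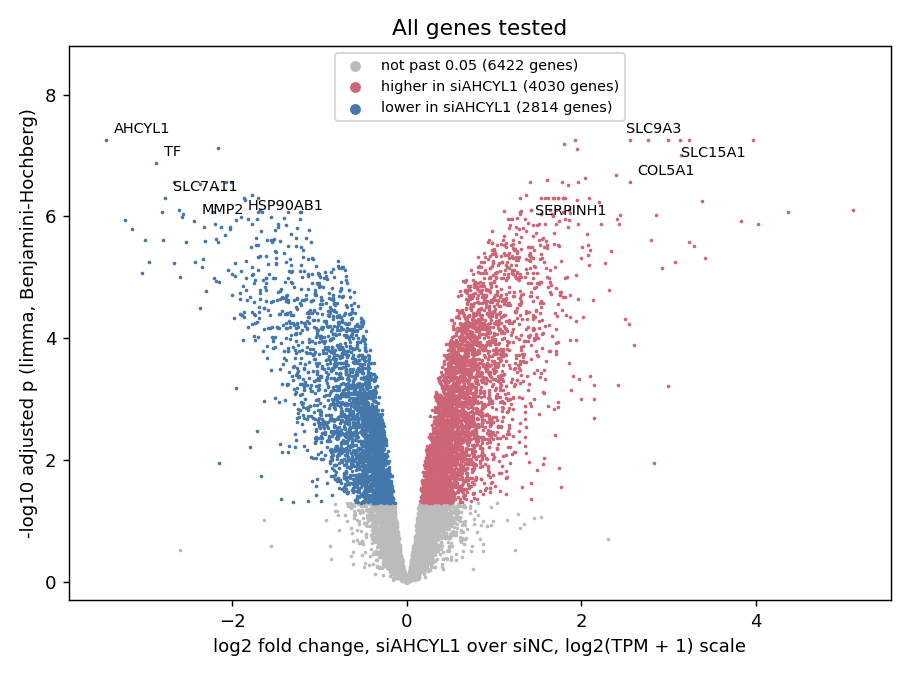
Log2 fold change on the log2(TPM + 1) scale (x axis) against -log10 of the limma adjusted p (y axis) for the 13266 genes tested, 1 point per gene. The 4030 higher genes are red, the 2814 lower genes blue and the rest grey, and AHCYL1 lies at -3.44.

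Of the 29 fixed lists tested, 5 were lower and 1 was higher after the AHCYL1 siRNA (camera adjusted p under 0.05). With a correlation estimated from the data no list passed, so none of these 6 calls held, and those adjusted p stand beside each list. Where no count adjusted over the list alone is given, it equalled that over all genes. The median, the mean and camera's direction differed in sign in 11 lists, and 0 of these passed.

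Cholesterol biosynthesis and SREBP target genes were lower, with 21 of 28 tested members down and 2 up, the same counts when adjusted over the list alone (median log2 fold change -0.53, camera adjusted p = 5.48e-07, adjusted p = 0.775 with an estimated correlation). SREBF2, the transcription factor that drives the pathway, fell from 119 ± 4.54 to 48.8 ± 3.54 TPM (-1.27). SCD (-1.21), the stearoyl-CoA desaturase, and DHCR7 (-1.02), an enzyme of the last steps of cholesterol synthesis, fell as well. LSS, lanosterol synthase, rose (0.65).

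NRF2 targets were lower, with 14 of 22 down and 1 up, and 15 down and 1 up when adjusted over the list alone (median -0.51, camera adjusted p = 2.65e-06, adjusted p = 0.775 with an estimated correlation). Besides SLC7A11, these were HMOX1, heme oxygenase 1 (51.8 ± 4.36 to 17.4 ± 0.96 TPM, -1.52), FTL, the ferritin light chain (1407 ± 26.7 to 817 ± 33.4 TPM, -0.78), and OSGIN1 (-1.22). AKR1B10 rose (0.95, adjusted p = 0.0328).

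HSF1 targets of the heat shock response were lower, with 13 of 20 down and 1 up, also when adjusted over the list alone (median -0.43, camera adjusted p = 0.000322, adjusted p = 0.934 with an estimated correlation). HSP90AB1, the cytosolic chaperone HSP90 beta, fell from 2940 ± 301 to 787 ± 86.7 TPM (-1.90). HSPB1 (-0.74) and FKBP4 (-0.67) fell. SERPINH1, an ER chaperone of collagen, rose from 30.2 ± 1.68 to 80.6 ± 2.57 TPM (1.39). HSP90AB1 carries GTATGCAA, in its 3′ UTR.

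Cytosolic ribosomal protein genes were lower, with 38 of 50 down and 0 up, and 39 down and 1 up when adjusted over the list alone (median -0.32, camera adjusted p = 3.16e-11, adjusted p = 0.388 with an estimated correlation). RPL12 fell from 3370 ± 61.8 to 2137 ± 68.2 TPM (-0.66), and RPL18 (-0.59), RPL19 (-0.53) and RPS13 (-0.51) fell. The list held between 12.1% and 12.4% of TPM in the control libraries and between 9.29% and 9.56% after the AHCYL1 siRNA. Ribosomal protein genes have many processed pseudogenes, so their single values are uncertain.

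Genes of the integrated stress response went both ways, with 15 of 30 down and 8 up, and 16 down and 8 up when adjusted over the list alone (median -0.28, camera adjusted p = 0.036, adjusted p = 0.934 with an estimated correlation). The falls included, besides SLC7A11, the serine and one-carbon enzymes PHGDH (265 ± 10.4 to 112 ± 2.17 TPM, -1.23), PSAT1 (-1.01) and SHMT2 (-0.75). ATF5, a transcription factor, rose (0.95). The call was lost under 5 other planned fits (adjusted p from 0.0586 to 0.103) and without siAHCYL1 replicate 1 (adjusted p = 0.0773).

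G1/S and DNA replication genes were higher, with 26 of 40 up and 1 down, also when adjusted over the list alone (median 0.32, camera adjusted p = 0.00131, adjusted p = 0.934 with an estimated correlation). E2F1, a transcription factor of S-phase entry, rose from 59.7 ± 1.55 to 131 ± 8.29 TPM (1.12), and CHAF1B (0.74), E2F2 (0.78) and UNG (0.72) rose. FEN1 fell (-0.36). Of 36 G2/M and mitosis genes, 7 rose and 5 fell (camera adjusted p = 0.706), among them NDC80 (0.96), MKI67 (0.60) and PRC1 (0.46) up and PTTG1, securin, down (-0.60). CHAF1B and PRC1 carry GTATGCA and rose.

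**Figure D3:**
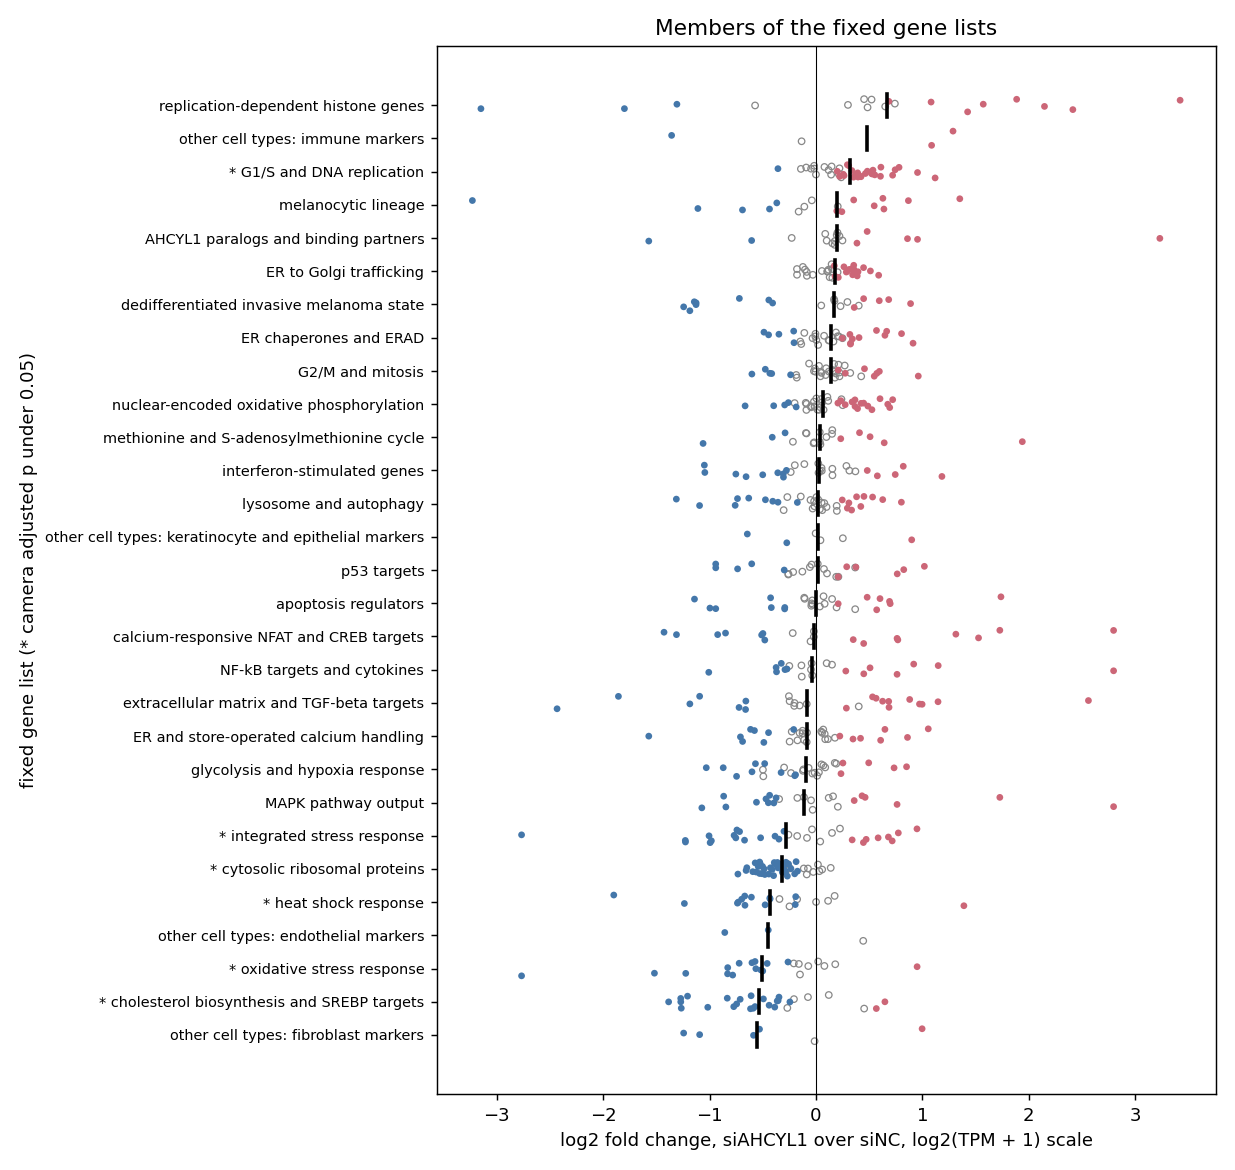
Log2 fold change on the log2(TPM + 1) scale (x axis) of each tested member of the 29 fixed lists (y axis), 1 point per gene, red or blue where adjusted p was under 0.05 and open where it was not, with a black line at the list's median. The lists marked with an asterisk passed camera, and 38 of the 50 ribosomal members are blue, with a median of -0.32.

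The ER lists did not pass as sets. Of 31 ER and store-operated calcium handling genes, 7 rose and 8 fell (camera adjusted p = 0.393). VDAC1, a mitochondrial outer membrane channel, fell (484 ± 6.46 to 300 ± 6.12 TPM, -0.69), and CALR, the ER calcium-binding chaperone calreticulin, rose (1154 ± 2.54 to 1809 ± 31.5 TPM, 0.65). Of 32 ER chaperone and degradation genes, 11 rose and 5 fell (camera adjusted p = 0.386). Besides CALR, CRELD2 (0.80), P4HB (0.66) and ERO1B (0.91) rose, and DNAJB11 fell (-0.49). Of 32 ER to Golgi trafficking genes, 16 rose and 0 fell (camera adjusted p = 0.0767), among them COPE (0.51), GOLGA2 (0.59), KDELR1 (0.36) and COPG1 (0.40). That list passed without siNC replicate 1 (adjusted p = 0.0418), with no filter (0.013), with the replicate block (0.0307) and with the length and GC trend removed (0.0486). In 12 of 16 refits it did not pass. Of 17 AHCYL1 paralogs and binding partners, 5 rose and 2 fell (camera adjusted p = 0.244), with SLC9A3, ITPR3 and RRM2 (0.95) up and ITPR1 down.

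The signalling and melanoma state lists held changes in both directions. Of 19 NFAT and CREB targets, 8 rose and 7 fell (camera adjusted p = 0.91), with CXCL8 (2.80), EGR1 (1.73) and EGR3 (1.53) up and PER1 down (-1.31). Of 23 MAPK output genes, 6 rose and 9 fell, or 10 fell when adjusted over the list alone (camera adjusted p = 0.34), with CXCL8 and EGR1, members here too, up and DUSP4 (-1.07) and ETV5 (-0.85) down. ETV5 carries GTATGCA. Of 17 melanocytic genes, 8 rose and 5 fell (camera adjusted p = 0.952), with S100B (1.35) and RAB27A (0.63) up and ACP5 (-1.11) down with DCT. Of 19 genes of the dedifferentiated state, 5 rose and 8 fell, or 6 and 8 when adjusted over the list alone (camera adjusted p = 0.706), with TGFBI (-1.19) and PDGFRB (-1.24) down and LOXL2 (0.68) and F2RL1 (0.89) up. Of 21 NF-kB targets, 7 rose and 6 fell (camera adjusted p = 0.863), with IL6 (0.76) and CXCL1 (1.15) up and IL1B (-1.01) down.

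Markers of other cell types were few and did not pass camera. Of 4 immune and blood cell markers tested, 2 rose and 1 fell (camera adjusted p = 0.706). The leukocyte genes LCP1 (42.6 ± 3.38 to 105 ± 8.56 TPM) and PTPRC (1.09) rose, and HBA1, an alpha-globin gene of red blood cells that has a near-identical copy, fell (-1.36). Of 6 fibroblast markers, 1 rose and 4 fell (camera adjusted p = 0.182), with LUM (1.00) up and COL1A1 (-1.09) down. Of 3 endothelial markers, 0 rose and 2 fell (camera adjusted p = 0.349), EGFL7 (-0.86) and KDR (-0.45). Of 6 epithelial markers, 1 rose and 2 fell (camera adjusted p = 0.779), KRT8 (0.90), CLDN4 (-0.65) and KRT18 (-0.27, adjusted p = 0.0442). The calls of KDR, KRT8 and KRT18 were each lost under at least 1 other setting. PTPRC and KRT8 carry GTATGCA, and KRT18 carries GTATGCAA.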

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

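Chosen after seeing the data were the fits without replicate 1 of both groups, with the length and GC trend removed, and without carriers of the 7-mers. Depth is unknown, so what it limits could not be set. The count of changed genes was 6844 and ranged from 5541 (without carriers of the 7-mers, fewer genes tested) to 7919 across settings, and with 1 library left out from 5566 to 6725. The count changed at least 2-fold was 1109 and ranged from 849 to 1508, and with 1 library left out from 1039 to 1099. Quantile normalization reversed 1 call, and no other refit reversed any. AHCYL1 stayed past the threshold in every fit, with log2 fold changes from -3.54 to -3.38. Of the list tests, 28 of 522 changed direction while past the threshold in neither fit. Whether the replicate numbers pair the samples is not settled. Same-numbered libraries deviated from their group means with correlations of 0.233, 0.001 and 0.154, and not every library correlated best with its own number. Replicate 1 of each group did correlate best with replicate 1 of the other, and both lay at the same end of the second principal component (15.04 and 17.57). With the replicate block, 7919 genes changed against 6844 without it, and AHCY passed (adjusted p = 0.0294).

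The integrated stress response lost its call with no filter (adjusted p = 0.0621), at 5 TPM (0.102), with median-of-ratios scaling (0.0686), quantile normalization (0.103) and no trend with robust moderation (0.0586), and ranged from 0.0179 to 0.0773 with 1 library left out. ER to Golgi trafficking passed with no filter (0.013), the replicate block (0.0307), the length and GC trend removed (0.0486) and fry (0.0442), and ranged from 0.0418 to 0.234 with 1 library left out. Histones ranged from 0.0332 to 0.384, passing without siNC replicate 2 (0.0332) or 3 (0.0378). With an estimated correlation, adjusted p became 0.388 for ribosomal proteins, 0.775 for cholesterol and NRF2 targets, and 0.934 for G1/S, HSF1 targets and the integrated stress response. Under fry, which does not compare a list with other genes, these passed as well: AHCYL1 partners (0.0143), ER chaperones (0.0301), oxidative phosphorylation (0.0347), endothelial (0.0442), fibroblast (0.0264) and immune and blood cell markers (0.00906) and histones (0.00793), and NF-kB targets passed in the opposite direction to camera (0.0264). For these changes of call, beyond the different question fry asks, the cause was not tested.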

Other observations

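Chosen only after results were seen were the comparison of G1/S with G2/M genes, the test of gene families, the fit without carriers of the 7-mers and the check on other abundant genes. Genes were grouped by symbol stem into 144 families, and 3 passed camera. RPL (adjusted p = 1.98e-06) and RPS (0.00229) were lower, and neither call held with an estimated correlation, under which every family had an adjusted p of 0.999. Collagen genes were the 1 family that rose (adjusted p = 0.00102, adjusted p = 0.999 with an estimated correlation, tested with COL4A3BP, which is not a collagen). Of 24 collagen genes, 18 rose, 2 fell and 4 did not pass, with a median log2 fold change of 0.91. COL5A1 rose from 84.9 ± 11.6 to 503 ± 20.7 TPM (2.56), COL11A1 from 499 ± 17.7 to 1518 ± 62.1 TPM (1.60) and COL18A1 from 542 ± 55.2 to 1128 ± 124 TPM (1.06), while COL25A1 (-0.76) and COL1A1 (-1.09) fell. COL11A1, COL18A1 and COL25A1 were chosen after their values were seen. In the fixed list of extracellular matrix and TGF-beta targets, 11 of 25 rose and 7 fell (camera adjusted p = 0.91), with SERPINE2 (-1.86) and MMP2 (-2.43) down. MMP2 carries GTATGCA.

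Of 40 nuclear-encoded oxidative phosphorylation genes, 15 rose and 5 fell (camera adjusted p = 0.44), with UQCRC2 (0.67) and NDUFB5 (0.60) up. Of 30 glycolysis and hypoxia genes, 5 rose and 9 fell (0.244), with PFKL (0.85) up and LDHA (837 ± 58.6 to 459 ± 68.0 TPM, -0.87) and HK1 (-0.60) down. Of 35 lysosome and autophagy genes, 10 rose and 9 fell (0.706), with BECN1 (0.80) up and ATG5 (-1.31) and LAMP2 (-1.09) down. HK1, ATG5 and LAMP2 carry GTATGCA, as does NDUFB5, which rose. In ATG5 and NDUFB5 it is part of GTATGCAA. Of 18 histone genes, 8 rose and 3 fell (0.244), and HIST1H2AC rose (2.41). Histone genes are near-identical copies, so reads may be split between them, and this list passed without siNC replicate 2 (0.0332). Of 27 interferon-stimulated genes, 5 rose and 9 fell (0.609), with STAT2 (0.74) up and TRIM22 (-1.04) down. Of 26 apoptosis regulators, 7 rose and 7 fell (0.91), with XIAP (0.70) up and BIK (-1.14) and BCL2 (-0.997) down. Of 23 p53 targets, 6 rose and 5 fell, or 5 and 5 when adjusted over the list alone (0.863), with BTG2 (1.02) up and PHLDA3 (-0.94) down. Of 19 methionine cycle genes, 5 rose and 3 fell (0.952), with NNMT (1.94) up and ADA (-1.06) down.

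A short sequence was found more often in the 3′ UTRs of genes that fell. Among 16244 7-mers in 12183 genes, 4 were associated with lower and 18 with higher fold changes beyond a bound of 4.52 in z. GTATGCA led on the lower side (z = -12.27, with -4.26 the lowest among 629 others of its base composition) and TCGGAGA on the higher side (6.25). Several of the 18 overlap, such as TCGAGAC with CGAGACC, so they are not 18 separate sites. Seed sites of the control siRNA, whose sequence is not given in the sources used here either, may show on the higher side. So may other sequences that many 3′ UTRs share, and neither was tested. GTATGCA overlaps the runner-up TATGCAA (z = -8.21) and occurs in the AHCYL1 mRNA, as do 23.39% of all 7-mers. The joined GTATGCAA, formed from the scan's 2 leading words, occurs there in the coding sequence of exon 12 of 17 at chromosome 1, 110018429 to 110018436. Of all 8-mers, 6.73% occur in this mRNA. The median log2 fold change was -0.29 in 288 genes with the 8-mer, -0.07 in 790 with GTATGCA but not the 8-mer, -0.0003 in 1105 with TATGCAA but not GTATGCA and 0.07 in 10000 with neither, so direct seed pairing of the AHCYL1 siRNA with other mRNAs is a candidate explanation for part of the falls, while its sequence is not given in the sources used here and a microRNA or protein that binds this sequence stays open. Of fallen genes searched, 15.12% carried GTATGCA (22.75% of those that fell at least 2-fold, 5.93% of risen ones). In the 3′ UTRs searched, direct pairing through it does not reach most of the falls. That follows from the number of carriers alone, since 1078 genes carry it against 2719 fallen genes searched. No other outcome was possible, so the fold changes did not test it. Pairing through other sequences or outside 3′ UTRs is not addressed by this share. Without carriers of either 7-mer 2079 genes were lower against 2814 with them, with 11083 genes tested against 13266. Leaving genes out lowers such a count by itself, so it does not show how many falls depend on these sites. Falls that follow indirectly from genes silenced through GTATGCA were not tested.

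Of 50 ribosomal protein genes 38 fell and 12 did not pass, a list call that ranged from 1.9e-14 to 0.0209 over the refits (adjusted p = 0.388 with an estimated correlation). Loss of AHCYL1 may bring this about, but so may the siRNA itself, since the design has 1 AHCYL1 siRNA treatment against 1 control treatment. A bias by length, GC content or expression is argued against, since 0.02% of 10000 lists matched on them had a median as low as -0.32 (matched lists 1250 bases and 870 TPM, ribosomal 1149 bases and 2016 TPM). The matched genes did not reach the level of the ribosomal ones, and 58 other genes of at least 1000 TPM had a median of -0.02. Their quartiles were -0.33 and 0.34, so some fell as far as the ribosomal median, and they were not matched on length or GC content. Shared reads with pseudogenes are argued against by the 13 members with at most 3 pseudogenes, whose median was -0.3177 (95% bootstrap interval -0.51 to -0.27).

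G1/S genes rose by 0.18 more in their medians than G2/M genes (value 0.1806), and 0.2% of 10000 reassignments of members gave as much. Genes are not independent replicates, but the difference of the 2 lists in each library lay between -0.13 and -0.08 in siNC and between 0.05 and 0.17 in siAHCYL1. A larger share of cells in all phases of the cycle that raises both lists alike is argued against. Whether the 2 lists respond equally to such a change was not tested. The G2/M median was also positive (0.14), but that list did not pass (camera adjusted p = 0.706). Its median deviation overlapped between the groups, at 0.056, -0.0648 and -0.1755 in siNC and 0.2127, 0.0075 and -0.065 in siAHCYL1. A rise of G2/M genes is thus not shown, and a larger share with an unequal response stays open. A change in the share of cells in G1 or S phase, or in E2F activity, may be behind the difference and was not tested. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many changed genes, 6844 against at most 1 in the others, and 10 splits are too few for a share under 0.05. Every other split mixes the 2 groups, so their difference enters its spread, and its count does not measure false calls.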
